A study of Mus musculus with 10 samples.

How the data were processed

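RNA from the laser-captured preoptic region of 10 LPS-treated mice was measured on 10 arrays, 1 per mouse, 5 labelled wild-type and 5 labelled mPGES-1 knockout. The titles give each array its group and replicate number, and the descriptions give a separate mouse number for each. RNA was amplified in 2 rounds and labelled with biotin, per the labels' protocols. The deposited values are probe set intensities on a linear scale, never below 0, and were made with GCOS, per the submitters' processing notes. The GCOS version, its settings and detection calls are not given in the sources used here. In the deposited table each array had the same mean intensity, 200.002, over probe sets without the lowest 2% and highest 2%, so the arrays had been scaled as a whole, and no other normalization was seen. This scaling leaves differences in the shape of the distribution between arrays in place, so bright and dim genes can shift against each other.

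Probe sets were named from a table that pairs them with the platform annotation, which can be old. Of 45101 probe sets, 64 were controls, 34945 named 1 gene, 932 named several and 9160 named none, and those that named several or none were given no gene. Of the probe sets with 1 gene, 34741 matched a RefSeq gene table (assembly GRCm38.p6) by Entrez ID, and 0 symbols changed. The deposited table names no build, so this gene table served for names and for neighbours of Ptges, and no coordinates are printed. Each of 18193 genes was represented by the probe set with the highest mean log2 value, with names ending in _x_at used if there was no other. The dimmest 40% of genes were left out, at a mean log2 value of 5.83, which left 10916.

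Values were tested as log2(intensity + 16), so fold changes are on that scale and understate the change of dim genes. The test was limma (lmFit, eBayes with an intensity trend), labelled knockout minus labelled wild-type, with genotype as the only term and a Benjamini-Hochberg adjusted p below 0.05. Dim genes named in the text but left out of the main test were taken from the same fit over all genes. The 26 gene lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, by fry and by an exact permutation test of the list mean over all 252 arrangements. A list needed 5 tested members, and the sex-linked list had fewer. Genes near Ptges were tested by Fisher's exact test. Analyses used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

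The design, tests, lists, other settings to try and the rule for named genes were set before the data were examined. The rule takes Ptges, up to 12 genes past the threshold in each direction by size of change, the genes with the smallest p to fill each direction up to 8, the 2 tested members of each list with the smallest p and other members past the threshold up to 4, and Ptger1 to Ptger4, Ptgs2, Il6, Il1b, Fos, Cirbp and Rbm3 whatever their p. Genes named outside this rule are said to be so, apart from members of the striatal lists, which were named after their values were seen. These settings were pseudocounts of 1 and 64, quantile normalization, median centring, other filters on dim genes, other uses of probe sets, array weights, no trend, the replicate number as a block, an adjusted p below 0.1, windows of 5 and 10 Mb and leaving out each array. After the data were seen, 7 were added: a block of arrays with and without signal from the poly-A spike-in RNAs, each of these sets of arrays alone, quantile normalization with that block, quantile normalization with array weights, the hybridization control signal as a covariate, and camera with an estimated correlation under each setting. Arrays were counted as having spike-in signal if it reached 100.

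No pair of arrays held the same values at more than 0.00443% of probe sets, so none was a copy of another. The Y-linked gene Eif2s3y was above Xist on all 10 arrays, between 7.37 and 8.93 against 4.47 to 6.71 on the log2 scale. The procedure was tested on simulated data with the arrays' own spread, 5 against 5 over 10916 genes, and recovered 44%, 66%, 90% and 94% of genes changed by log2 0.75, 1, 1.5 and 2. In that test 6.96% of the calls were false, 1 gene was called with no change present, and camera called 5 of 5 shifted and 0 of 15 unshifted lists. Genes were simulated as independent of each other and without array-wide differences. The test therefore does not show how often limma or camera calls falsely on the real arrays, where members of a list can move together. Replicates are separate mice, so p-values reflect the spread between mice together with dissection, amplification and array effects.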

Results

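Gene expression was measured in the preoptic region of the hypothalamus, the brain area in which prostaglandin E2 acts on neurons that control body temperature. All 10 mice, of the DBA1/lacJ strain, had been given 120 µg/kg of the bacterial cell wall component lipopolysaccharide (LPS) into the peritoneum, and brains were removed 5 h later. Of these mice, 5 were labelled wild-type and 5 were labelled knockout for microsomal prostaglandin E synthase-1 (mPGES-1, gene Ptges), the inducible enzyme that makes prostaglandin E2 during inflammation. The region was cut out by laser capture microdissection, the RNA was amplified in 2 rounds, and each mouse gave 1 array of 45101 probe sets. The question was which transcripts of the preoptic region differ between the genotypes in LPS-treated mice. No mice without LPS were analysed here, so the response to LPS itself was not measured, and the number of arrays limits the precision of every value.

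The Ptges transcript was not lower in the arrays labelled knockout. Probe set 1439747_at gave a signal of 49.96 ± 24.5 (SD, n = 5) in the arrays labelled knockout and 4.54 ± 3.09 (SD, n = 5) in those labelled wild-type, with no overlap between the groups (two-sided exact permutation test, p = 0.0079, the smallest 5 against 5 arrays can give; Benjamini-Hochberg adjusted over the 3 Ptges probe sets, 0.024). Over all probe sets of the array the limma adjusted p of this probe set was 0.111. The other 2 probe sets gave 40.2 ± 21.5 against 13.4 ± 13.6 (1449449_at, exact p = 0.071) and 37.3 ± 15.9 against 30.7 ± 19.7 (1449450_at, exact p = 0.55). All 3 were dim, between percentiles 42.0 and 52.1 of mean signal. The labels do not say which part of the gene was deleted, so a probe set outside that part checks no label. Because the transcript went against a simple loss, the groups are called labelled knockout and labelled wild-type throughout, and every direction rests on those labels.

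Of 10916 genes tested, 2 rose and 6 fell in the mice labelled knockout (limma, Benjamini-Hochberg adjusted p below 0.05). The risen genes were both neuronal. Tac1, which encodes the precursor of substance P and neurokinin A, was 2.67-fold higher (log2 difference 1.42, SE 0.22, limma adjusted p = 0.031, n = 5 per group). Synpr, which encodes the synaptic vesicle protein synaptoporin, was 2.74-fold higher (log2 1.46, SE 0.25, limma adjusted p = 0.043). The largest fall was in Csf2ra, the alpha chain of the receptor for granulocyte-macrophage colony-stimulating factor, at log2 -0.99 (SE 0.17, limma adjusted p = 0.043). Complex I subunit genes of the respiratory chain made up 2 of the other falls, Ndufv3 at -0.75 (SE 0.10, limma adjusted p = 0.021) and Ndufb11 at -0.59 (SE 0.10, limma adjusted p = 0.044). Stmn1, encoding the microtubule regulator stathmin, was at -0.75 (SE 0.13), Pabpn1, encoding the nuclear poly(A)-binding protein, at -0.74 (SE 0.11) and Hcfc1r1 at -0.66 (SE 0.11), with limma adjusted p of 0.043, 0.031 and 0.043. In all 8 genes the 5 arrays of one group lay wholly above the 5 of the other. Of the 2 Stmn1 probe sets above the filter, 1 went the opposite way.

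**Figure D1:**
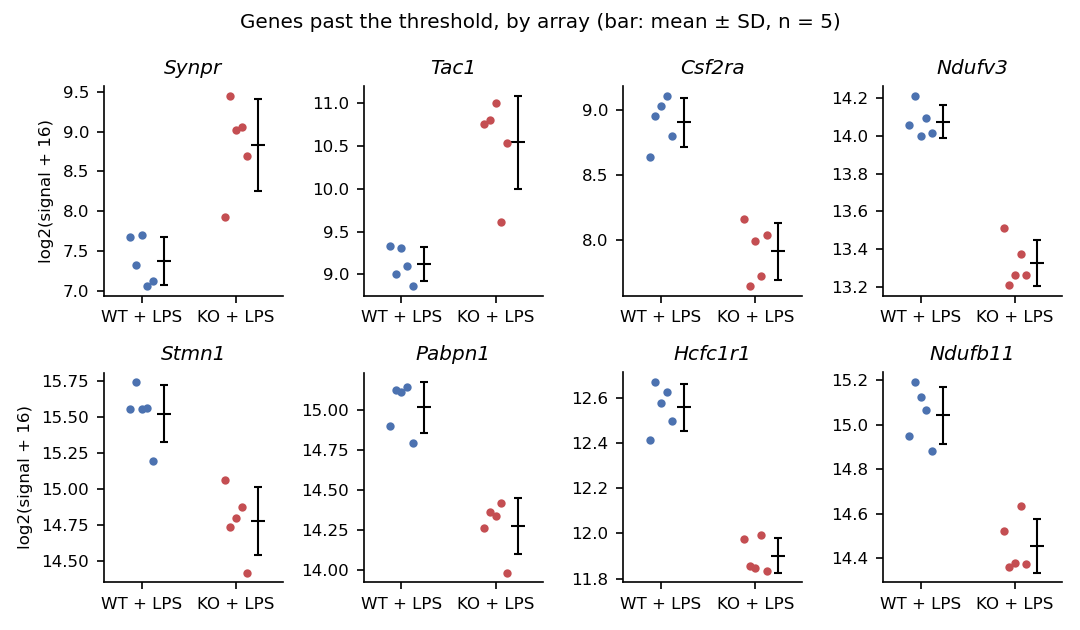
Points are single arrays of the 8 genes past the threshold, on the log2(signal + 16) scale, with wild-type in blue and knockout in red as labelled, and the bar beside each group is the mean ± SD (n = 5). The groups do not overlap in any of the 8 genes, and Tac1 averages 10.54 in the arrays labelled knockout against 9.12 in those labelled wild-type.

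The 8 calls were near the threshold and depended on the setting, among others on single arrays, normalization and the choice of probe set. Leaving out WT replicate 1, 2 or 4 or KO replicate 2, 3 or 5 left 0 genes past the limma threshold (between 1545 and 1906 genes at unadjusted p below 0.05), and leaving out WT replicate 3, WT replicate 5 or KO replicate 1 gave 39, 29 and 31, with all 8 among them. Leaving out KO replicate 4 gave 5, of which 3 (Tac1, Ndufv3 and Pabpn1) are among the 8, and Pde10a and Arpp21 are not. With the mean of a gene's probe sets only Ndufv3 passed limma's threshold, and Tac1 was at 0.62 (limma adjusted p = 0.173), Csf2ra at -0.63 (0.147), Hcfc1r1 at -0.43 (0.133), Pabpn1 at -0.37 (0.189) and Stmn1 at -0.16 (0.633), while Synpr stayed at 1.46 (0.060). The limma test also left 0 genes past its threshold without an intensity trend (smallest adjusted p = 0.075, folds unchanged). With the hybridization controls as a covariate 0 genes passed limma's threshold (smallest adjusted p = 0.188, with Tac1 at 1.53, Stmn1 at -0.42 and Pabpn1 at -0.46). With no filter on dim genes 3 passed, Tac1 and Ndufv3 of the 8 and Pkdrej, named after its value was seen. With the replicate number as a block 2 passed, Pabpn1 of the 8 and Pde10a. Median centring, which shifts all genes up in the arrays labelled knockout, gave 1053 genes, 1027 higher and 26 lower, among them all 8. Quantile normalization left 0 genes past the limma threshold (smallest adjusted p = 0.075, 1638 genes at unadjusted p below 0.05). There Tac1 at 1.35, Synpr at 1.44 and Csf2ra at -1.05 kept their size, and Hcfc1r1 was at -0.56 and Ndufv3 at -0.45, while Stmn1 was at -0.12, Pabpn1 at -0.24 and Ndufb11 at -0.06. RNA spike-ins added before labelling gave signal on 7 arrays and none on WT replicates 2 and 5 and KO replicate 3. With this difference as a block, 16 genes passed, among them all 8, with Tac1 at 1.43 and Csf2ra at -0.99. Within the 7 arrays with spike-in signal 0 genes passed limma's threshold (1500 at unadjusted p below 0.05), and Tac1 was at 1.18, Synpr at 1.31 and Csf2ra at -1.03. Within the 3 arrays without it, of which 1 is labelled knockout and was assumed to vary like the other 2, 1 gene passed, the transthyretin gene Ttr, named after its value was seen.

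The difference between groups was broad and mostly below the threshold for single genes. At unadjusted p below 0.05 there were 1883 genes, 905 higher and 978 lower, where chance gives 545.8 on average. Genes that move together widen the spread of that chance count. At an adjusted p below 0.1 there were 346 genes. The groups did not overlap in 511 genes, or 4.68% of those tested, against 0.794% by chance. In 99 other splits of the same arrays into 5 and 5 the count at unadjusted p below 0.05 had a median of 418 and reached 1759 with 1 array of each group exchanged and 1441 with 2 of each. Genes that came nearest to passing on the higher side were Ranbp2 at 0.89 and Rab40b at 1.36, with limma adjusted p of 0.051 and 0.052. They were followed by Secisbp2l at 0.93, Umad1 at 1.11, Usp33 at 0.67 and the neurexin gene Nrxn3 at 0.68, where 2 of 4 probe sets went the opposite way. On the lower side they were Tom1 at -0.65 and the 14-3-3 gene Ywhab at -0.73, both with a limma adjusted p of 0.051.

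Of 25 gene lists fixed before the data were examined and large enough to test, 5 differed between the groups by camera with a preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.646 for each of the 5). Under each other setting in which lists were tested, too, 0 passed with an estimated correlation, in a check made after the data were seen. List means below are relative to the mean of the other tested genes, and medians are not, because centring the arrays on their medians moved the median difference of the tested genes from -0.01 to 0.27. By fry, 0 lists moved one way after adjustment and 10 changed in either direction, the 5 of camera and 5 others named below. Fry in either direction does not compare a list with other genes, and 1883 of the 10916 tested genes had an unadjusted p below 0.05. Also, 0 list means passed the exact permutation test after adjustment over the lists.

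The joint list of striatal and septal markers averaged higher in the mice labelled knockout, but not in every member or every mouse. The striatum and septum lie next to the preoptic region, and 11 of 15 tested members were higher, by a mean of 0.51 (camera adjusted p = 0.013; adjusted p = 0.646 with an estimated correlation). Of the members, 1 passed over all genes tested, Tac1, and 5 higher and 1 lower passed when adjusted over the list alone. Pde10a, a phosphodiesterase gene abundant in striatal projection neurons, was at 1.60 (SE 0.33, limma adjusted p = 0.056), the dopamine D1 receptor gene Drd1 at 1.24 (SE 0.44) and the enkephalin precursor gene Penk at 0.93 (SE 0.34). The 4 members on the other side were Dlk1 at -0.43 (SE 0.14), Rgs9 at -0.25 (SE 0.22), Trpc4 at -0.09 (SE 0.21) and Zic1 at -0.0041 (SE 0.18). The mean list score was 8.99 ± 0.45 (SD, n = 5) in mice labelled knockout and 8.49 ± 0.14 in mice labelled wild-type (exact permutation test, p = 0.079). The list's camera adjusted p was 0.055 without KO replicate 3, 0.088 with the lowest 60% of genes left out, 0.063 with quantile normalization and array weights, and 0.125 within the 7 arrays with spike-in signal, with a difference of 0.44.

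Genes of GABA and glutamate transmission were also higher, 18 of 25 tested members by a mean of 0.21 (camera adjusted p = 0.042; adjusted p = 0.646 with an estimated correlation). Of these genes 0 passed over all genes tested and 2 higher passed when adjusted over the list alone. The GABA-A receptor subunit gene Gabra4 was at 0.89 (SE 0.22, limma adjusted p = 0.073), and Gad1, which encodes a GABA-synthesizing enzyme, at 0.97 (SE 0.28, limma adjusted p = 0.103). The list's camera adjusted p was 0.170 without WT replicate 4, 0.104 without KO replicate 2, 0.128 without KO replicate 3, 0.064 with no filter on dim genes, 0.085 with the lowest 60% left out, 0.115 with the mean of a gene's probe sets and 0.125 within the 7 arrays with spike-in signal. It was 0.152 with quantile normalization, 0.094 and 0.153 when the spike-in block or array weights were added to that, and 0.096 with the hybridization controls as a covariate. The list score moved with the striatal and septal score, with which it shares 0 genes. With group means removed, Pearson r was 0.646 and Spearman rho 0.697 over 10 arrays (permutation p = 0.043 and 0.031, 1 relation, looked at after both lists' results were seen). The r was 0.449 without the 2 arrays farthest from the median, so the relation rests in part on those, and 0.526 within the 7 arrays with spike-in signal.

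Heat shock and cold-inducible genes were higher, 14 of 17 tested members by a mean of 0.20 (camera adjusted p = 0.035; adjusted p = 0.646 with an estimated correlation). Of these genes 0 passed over all genes tested and 3 higher passed when adjusted over the list alone. The list score was 10.59 ± 0.08 (SD, n = 5) against 10.40 ± 0.08 (exact permutation test, p = 0.0079; 5 of 5 arrays labelled knockout lay above every array labelled wild-type). The inducible chaperone gene Hspa1b was at 0.90 (SE 0.23, limma adjusted p = 0.073) and the endoplasmic reticulum chaperone gene Hspa5 at 0.52 (SE 0.14, limma adjusted p = 0.088; 1 of 3 probe sets opposite). Cirbp, a cold-inducible RNA-binding protein gene, went the other way at -0.81 (SE 0.34, limma adjusted p = 0.239), and Rbm3 has no value here because its probe sets name several genes. The list's camera adjusted p was 0.067 without WT replicate 4, 0.051 without WT replicate 5, 0.091 without KO replicate 1, 0.055 without KO replicate 3, 0.053 with the lowest 60% of genes left out and 0.067 within the 7 arrays with spike-in signal.

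Ribosomal protein and oxidative phosphorylation genes, among the brightest on these arrays, were lower in the mice labelled knockout as deposited. Of 24 tested ribosomal protein genes 21 were lower, by a mean of -0.23 (camera adjusted p = 0.0013; adjusted p = 0.646 with an estimated correlation). Of 41 oxidative phosphorylation genes 26 were lower, by a mean of -0.11 (camera adjusted p = 0.015; adjusted p = 0.646 with an estimated correlation). Over all genes tested 0 members of either list passed, and adjusted over the list alone 6 ribosomal genes were lower, and 12 oxidative phosphorylation genes were lower and 1 higher. Rpsa was at -0.68 (SE 0.13) and Rps3 at -0.60 (SE 0.13, and 0.05 with quantile normalization), and the respiratory chain genes Cox6a1 and Ndufc1 were at -0.63 (SE 0.12) and -0.58 (SE 0.12). Quantile normalization ended both calls, with the ribosomal list at -0.11 (camera adjusted p = 0.407) and the oxidative phosphorylation list turned to 0.02 (camera adjusted p = 0.721). The oxidative phosphorylation call also ended with no filter on dim genes, at -0.03 (camera adjusted p = 0.228), with median centring (0.058) and with the mean of a gene's probe sets, where the list turned to 0.0085 (0.821). Within the 7 arrays with spike-in signal the lists were at -0.11 and -0.06, with camera adjusted p of 0.167 and 0.149.

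**Figure D2:**
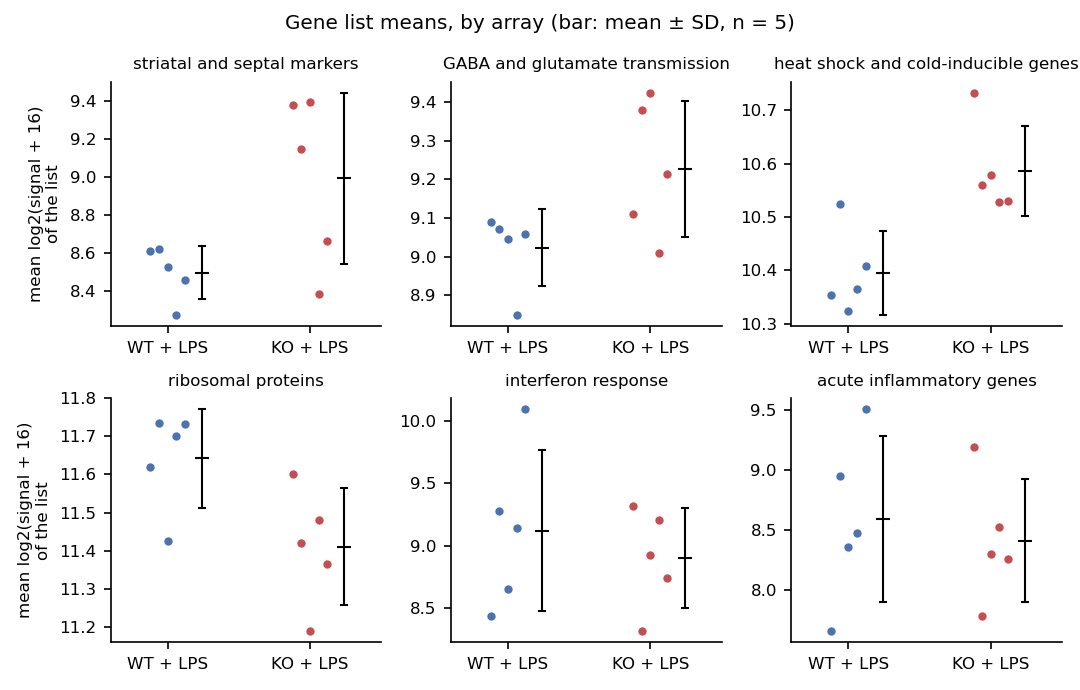
Points are the mean log2(signal + 16) of all tested members of a gene list on single arrays, with wild-type in blue and knockout in red as labelled, and the bar beside each group is the mean ± SD (n = 5). The heat shock score averages 10.59 in the arrays labelled knockout against 10.40, and the interferon score overlaps between the groups, at 8.90 ± 0.40 and 9.12 ± 0.64.

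Inflammatory gene groups did not pass by genotype as deposited, though some settings called them. Of 33 tested interferon response genes 26 were lower in mice labelled knockout, by a mean of -0.21 (camera adjusted p = 0.080), with list scores of 8.90 ± 0.40 (SD, n = 5) against 9.12 ± 0.64 (exact permutation test, p = 0.57). Irf1, an interferon-induced transcription factor gene, was at -0.74 (SE 0.19, limma adjusted p = 0.080) and the peptide transporter gene Tap1 at -0.60 (SE 0.23). Without WT replicate 5 the list was at 0.03 and within the 7 arrays with spike-in signal at 0.16, so its direction turned. Camera adjusted p for this list was 0.0016, 0.0097, 0.013 and 0.015 without WT replicate 1, WT replicate 3, KO replicate 1 and KO replicate 4, and 0.0059 with median centring and 0.015 with array weights. It was 0.0082 with quantile normalization and array weights, at -0.34, and 6.5e-06 with the hybridization controls as a covariate, at -0.56. None of these calls held with an estimated correlation (adjusted p = 0.670 to 0.949; as deposited the correlation was 0.613 and the adjusted p 0.960). Of 31 acute inflammatory genes 22 were lower, by a mean of -0.17 (camera adjusted p = 0.267), and 0 passed, both over all genes tested and adjusted over the list alone. Its camera adjusted p was 0.0022 without WT replicate 1, 0.013 without KO replicate 1, 0.015 with median centring and 0.010 with the hybridization controls as a covariate (-0.42), but none of these calls held with an estimated correlation (adjusted p = 0.753 to 0.942; as deposited the correlation was 0.525 and the adjusted p 0.960). Its direction turned without WT replicate 5, to 0.06, and within the 7 arrays with spike-in signal, to 0.29. Within this list Bcl3 was at -0.70 (SE 0.28) and Nfkbia at -0.42 (SE 0.18; 2 of 5 probe sets opposite). Il1b, which was too dim for the main test, was at -0.997 (SE 0.32, limma adjusted p = 0.180) and Il6 at -0.15 (SE 0.49, and 0.08 with quantile normalization), also too dim.

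Prostanoid genes other than Ptges showed no shared direction, with 7 of 14 tested members higher and 7 lower (mean 0.01, camera adjusted p = 0.995). The prostaglandin E2 receptor genes were at 0.42 (Ptger3, SE 0.22, 95% interval -0.04 to 0.89) and -0.36 (Ptger4, SE 0.23, interval -0.84 to 0.11), with limma adjusted p of 0.333 and 0.425. Ptger2 was at 0.08 (SE 0.25) and the dim Ptger1 at -0.07 (SE 0.25, and 0.08 with quantile normalization). Ptgs2, which encodes the inducible cyclooxygenase, was at 0.08 (SE 0.30, interval -0.56 to 0.71), and the carbonyl reductase gene Cbr1 at -0.32 (SE 0.16).

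Lists of neuronal signalling and regulation did not pass by camera. By fry 3 of them changed in either direction, cAMP and PKA signalling (fry adjusted p = 0.021), neuropeptides (0.028) and thermoregulatory and hormone receptors (0.042). At unadjusted p below 0.05 these lists held 4 higher and 3 lower of 35 members, 3 and 1 of 23, and 2 and 1 of 20. Of all 10916 tested genes 1883 had such a p, so fry does not set these lists apart from other genes. Immediate early genes, of which 10 were higher and 14 lower, had a camera adjusted p of 0.995, with Fos at -0.29 (SE 0.23), Homer1 at 1.37 (SE 0.40) and Ier3 at -0.73 (SE 0.21), and their median, -0.05, and mean, 0.04, differed in sign. Adjusted over the list alone 2 immediate early genes were higher and 1 lower. Neuropeptide genes had a mean of 0.11 and a median of -0.03 (camera adjusted p = 0.745), and Tac1, also on this list, was the 1 member that passed over all genes tested and adjusted over the list alone. The cAMP and PKA signalling list and the list of thermoregulatory and hormone receptors had the same camera adjusted p of 0.745. In these lists Rapgef3, a cAMP-activated exchange factor gene, was at -0.62 (SE 0.18), the nociceptin receptor gene Oprl1 at 0.69 (SE 0.25) and the glucocorticoid receptor gene Nr3c1 at 0.40 (SE 0.16). Glucocorticoid-responsive genes had a camera adjusted p of 0.745, a mean of -0.04 and a median of 0.04, with Fam107a at -0.59 (SE 0.12) and the metallothionein gene Mt2 at -0.73 (SE 0.23). Circadian clock genes had a camera adjusted p of 0.995, a mean of -0.0045 and a median of 0.01, with Nr1d2 at 0.74 (SE 0.19) and Csnk1d at -0.59 (SE 0.20; 2 of 4 probe sets opposite).

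Markers of cell types and neighbouring tissue other than striatum and septum did not pass by camera. By fry endothelial (fry adjusted p = 0.028) and neuron markers (0.048) changed in either direction, in a test that does not compare them with other genes. At unadjusted p below 0.05 they held 0 higher and 3 lower of 15 members and 3 higher and 2 lower of 19, beside 1883 of all 10916 tested genes. Of 16 tested microglia and macrophage markers 14 were lower (mean -0.21, camera adjusted p = 0.083), with Csf1r at -0.58 (SE 0.15) and Tyrobp at -0.38 (SE 0.19). Of 15 endothelial markers 11 were lower (mean -0.19, camera adjusted p = 0.114), with the glucose transporter gene Slc2a1 at -0.47 (SE 0.13) and Esam at -0.87 (SE 0.22), and adjusted over the list alone 2 were lower. The camera adjusted p of these microglial and endothelial lists was 0.0097 and 0.034 without WT replicate 3, 0.016 and 0.036 without KO replicate 4, and 0.039 and 0.047 with median centring, and none of these calls held with an estimated correlation (adjusted p = 0.430 to 0.789; as deposited the correlations were 0.228 and 0.144 and both adjusted p 0.960). Neuron markers had a camera adjusted p of 0.995, a mean of -0.01 and a median of 0.04, with Snap25 at 0.60 (SE 0.17) and Syp at -0.67 (SE 0.24). The astrocyte list had a camera adjusted p of 0.832, with 9 members higher and 11 lower (mean -0.02), and its smallest p in Gfap at -0.73 (SE 0.16) and Aldoc at -0.29 (SE 0.11). Oligodendrocyte markers (0.717) had Ugt8a at 0.81 (SE 0.23) and Bcas1 at -0.43 (SE 0.17), and oligodendrocyte precursor markers (0.976) had Pdgfra at 0.36 (SE 0.18) and Cspg5 at -0.43 (SE 0.23). Mural (0.502), meningeal (0.706), ependymal (0.745), blood cell (0.485) and cortical and thalamic (0.745) lists, given with their camera adjusted p, did not pass camera either (meningeal without KO replicate 4, 0.036, and 0.586 with an estimated correlation of 0.412). In this order 4, 4, 7, 0 and 10 of their tested members were higher and 6, 7, 7, 7 and 5 lower. Their leading members were Notch3 at -0.54 (SE 0.22), Higd1b at -0.44 (SE 0.22), Slc6a13 at -0.60 (SE 0.24), Foxc1 at -0.38 (SE 0.24), Enkur at -0.68 (SE 0.22), Otx2 at -0.70 (SE 0.24), Hbb-b2 at -0.58 (SE 0.27), S100a8 at -0.56 (SE 0.58), Emx1 at -0.73 (SE 0.28) and Synpo2 at 0.49 (SE 0.24).

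A knockout bred into another strain can carry DNA of the first strain around the targeted gene. Of 229 tested genes within 20 Mb of Ptges on chromosome 2, 38 had an unadjusted p below 0.05, or 16.6%, against 17.3% of the 10687 tested genes elsewhere (odds ratio 0.953, 95% interval 0.652 to 1.36, two-sided Fisher's exact test, p = 0.86). The p of fry for change of these genes in either direction was 7.3e-06, a test that does not compare them with other genes. The genes with the smallest p in this window were Sptan1, at -0.51, Arrdc1, at -0.77, and Abi1, at 0.61, with limma adjusted p of 0.056, 0.072 and 0.082, and they are named after their values were seen. With median centring the odds ratio was 0.620 (Fisher's exact test, p = 0.0027).

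The arrays themselves differed between groups. The median signal was 27.6 ± 2.00 (SD, n = 5) in arrays labelled knockout and 37.0 ± 4.83 in arrays labelled wild-type (exact permutation test, p = 0.0079; adjusted over the array measures, 0.026). The 500 brightest probe sets held 40.4 ± 1.64% and 47.2 ± 2.83% of the signal (exact p = 0.0079, adjusted 0.026), and hybridization controls averaged log2 10.61 ± 0.40 and 11.49 ± 0.56 (exact p = 0.040, adjusted 0.086). The ratios of 3' to 5' signal, which rise with RNA breakdown and amplification, were 41.0 ± 8.20 and 37.2 ± 11.1 for Gapdh (exact p = 0.49). With the tested genes in 10 bins by signal level, the median difference between groups was -0.17 in the dimmest bin, reached 0.10 in bin 7 and was -0.08 in the brightest bin.

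**Figure D3:**
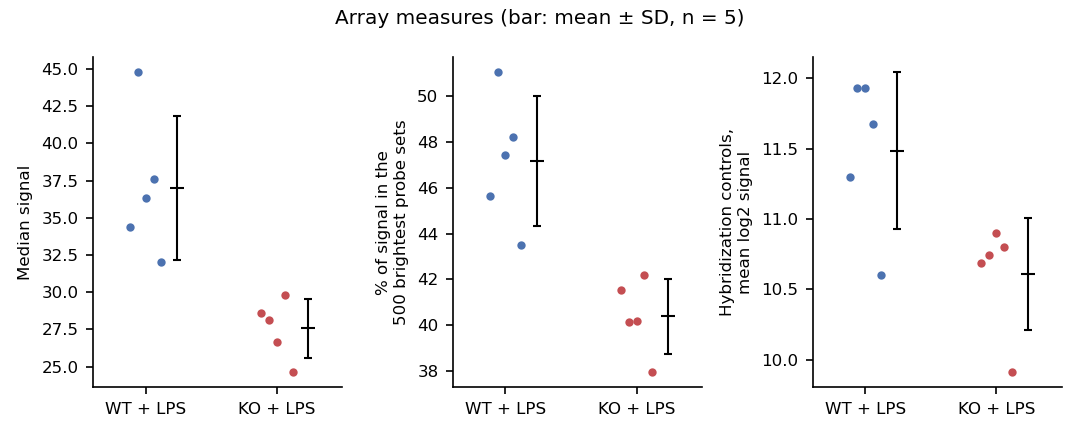
Points are single arrays, with wild-type in blue and knockout in red as labelled, and the bar is the mean ± SD (n = 5). The panels give the median signal, the percent of signal in the 500 brightest probe sets and the mean log2 signal of the hybridization controls, which average 27.6, 40.4 and 10.61 in arrays labelled knockout and 37.0, 47.2 and 11.49 in arrays labelled wild-type.

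**Figure D4:**
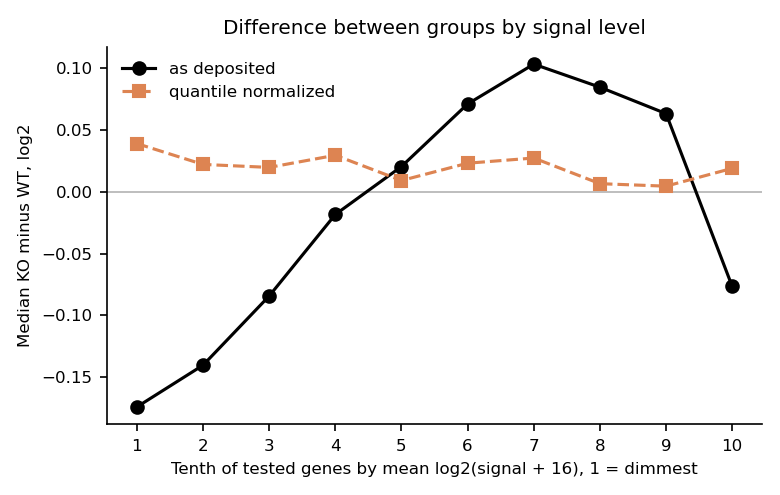
The x axis gives 10 equal bins of tested genes by mean log2(signal + 16), from the dimmest to the brightest, and the y axis is the median log2 difference, labelled knockout minus labelled wild-type, for values as deposited and after quantile normalization. As deposited the line runs from -0.17 through 0.10 to -0.08, and after quantile normalization it lies between 0.00 and 0.04.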

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

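In 17 of 210 groups of 5 arrays, 1 array stood apart from the other 4 by more than Dixon's 95% limit for its gap over the range (0.71), where chance alone gives about 10.5. This test was set before the data were examined, and no explanation of these values was tested.

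Among genes, on the log2(signal + 16) scale, KO replicate 1 stood apart in 4 of them: Cbr1 at 8.17 (next array 7.78), Irf1 at 7.95 (7.41) and Slc6a13 at 5.90 (5.60), all high, and Pdgfra low at 9.06 (9.55). KO replicate 3 was high in Homer1 at 11.51 (10.17), and KO replicate 5 was low in Slc2a1 at 11.41 (11.68). WT replicate 2 was high in Ier3 at 9.55 (9.10), and WT replicate 4 was low in Hspa1b at 8.10 (8.86). WT replicate 5 was low in Slc2a1 at 11.71 (12.16) and high in Notch3 at 8.04 (7.37).

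Among gene list means, WT replicate 4 was high in neuropeptides at 8.02 (next array 7.95) and low in GABA and glutamate transmission at 8.85 (9.04), and WT replicate 5 was high in mural cell markers at 7.96 (7.61). KO replicate 1 was high in heat shock genes at 10.73 (10.58), and KO replicate 3 was high in circadian clock genes at 8.63 (8.31). Among array measures, KO replicate 5 had low hybridization controls, at log2 9.91 (10.69), and WT replicate 3 a high ratio of 3' to 5' signal of actin, at 354.9 (156.3).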

How the results depend on the processing

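The added settings (the poly-A spike-in block, arrays with or without spike-in signal, quantile normalization with that block or with array weights, the hybridization control covariate, and camera with an estimated correlation under each setting other than as deposited) were chosen after the data were seen, and the rest before. Under other settings, 477 differences of gene lists and 1614 of named genes kept their direction and their side of the threshold, 28 and 129 lost a call, 19 and 82 gained one, and 75 and 27 reversed. The 8 called genes kept their direction under every setting run, and the cause of the changes given here was not tested unless named.

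The count of genes past the limma threshold, 8 with 2 higher and 6 lower (1883 at unadjusted p below 0.05), was 24 with a pseudocount of 64, 3 with no filter on dim genes (Tac1 and Ndufv3 kept, Pkdrej added after its value was seen), 65 with the lowest 60% left out, 1 with the mean of a gene's probe sets (Ndufv3, with Tac1 at 0.62 and Stmn1 at -0.16), 112 with array weights, 346 at an adjusted p below 0.1 and 16 with the poly-A spike-in block. It was 1053 with median centring, where 97.53% of calls were higher against 25% as deposited, since centring on the median moved all genes up in the arrays labelled knockout. The limma count was 0 with quantile normalization (1638 at unadjusted p below 0.05), 0 with all probe sets tested (5696, in a test of more features), 0 without a trend (1883), 0 with only the arrays with spike-in signal (1500, in fewer arrays), 0 with quantile normalization and the spike-in block (1603), 0 with quantile normalization and array weights (1883) and 0 with the hybridization control covariate (1278). Only the arrays without spike-in signal gave 1, with 1 array labelled knockout whose spread was assumed to be that of the 2 others. Leaving out each array gave 0 to 39.

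The count of lists past the camera threshold, 5, was 2 with quantile normalization, alone, with the spike-in block or with array weights, 8 with median centring, 3 with no filter, 2 with the lowest 60% left out, 3 with the mean of probe sets, 6 with array weights, 6 with the hybridization control covariate, 0 with only the arrays with spike-in signal and 13 with only the 3 arrays without it. It was 0 with an estimated correlation, as deposited and under each setting in which lists were tested (added after the data were seen), and 0 by fry and by the exact permutation test of the list mean, and 2 to 9 when each array was left out.

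The replicate numbers do not pair the mice: same-numbered arrays had correlations of -0.12, -0.05, -0.13, 0.07 and -0.05, each lower than the highest with another number. With the replicate number as a block 2 genes passed, Pabpn1, shared with the 8, and Pde10a, and 5 lists passed.

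The Ptges probe set 1439747_at passed with median centring, at 1.88 (limma adjusted p = 0.014, over its settings 0.014 to 0.502). The odds ratio near Ptges, 0.953, was 0.620 with median centring and went above 1 at 1.02 with quantile normalization, 1.09 with no filter, 1.25 with the lowest 60% left out, 1.12 with the mean of probe sets, 1.11 without a trend and 1.10 with only the arrays with spike-in signal. It was 0.715 and 0.902 at 5 and 10 Mb.

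Differences that turned direction, none of them past the threshold after turning, are given by setting. With a pseudocount of 64 prostanoid genes were at -0.021. With quantile normalization glucocorticoid-responsive genes were at 0.024, neuron markers at 0.0013, oxidative phosphorylation at 0.025, Rps3 at 0.045, Ptger1 at 0.083 and Il6 at 0.077. With median centring Ptger1 was at 0.21 and Il6 at 0.13, by the common upward shift of all genes under that setting. With no filter prostanoid genes were at -0.0098, thermoregulatory and hormone receptors at -0.0080, glucocorticoid-responsive genes at 0.043, circadian clock genes at 0.082, neuron markers at 0.073, astrocyte markers at 0.065, meningeal markers at 0.0032 and ependymal markers at 0.0031. With the lowest 60% left out prostanoid genes were at -0.21, immediate early genes at -0.015 and ependymal markers at 0.0085. With the mean of probe sets thermoregulatory and hormone receptors were at -0.033, circadian clock genes at 0.035, meningeal markers at 0.053, ependymal markers at 0.021, oxidative phosphorylation at 0.0085 and Nr3c1 at -0.0996. With array weights astrocyte markers were at 0.0068.

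With the poly-A spike-in block glucocorticoid-responsive genes were at 0.015, circadian clock genes at 0.027, neuron markers at 0.017, oligodendrocyte precursor markers at -0.0073, Ptger1 at 0.0071 and Il6 at 0.0058. With only the arrays with spike-in signal acute inflammatory genes were at 0.29, interferon response at 0.16, glucocorticoid-responsive genes at 0.075, astrocyte markers at 0.063, oligodendrocyte precursor markers at -0.0091, mural cell markers at 0.0061, meningeal markers at 0.14, Ptger1 at 0.067, Il6 at 0.69 and Fos at 0.059. With quantile normalization and that block glucocorticoid-responsive genes were at 0.075, circadian clock genes at 0.0064, neuron markers at 0.025, oligodendrocyte precursor markers at -0.019, meningeal markers at 0.050, oxidative phosphorylation at 0.032, Rps3 at 0.048, Ptger1 at 0.15 and Il6 at 0.23. With quantile normalization and array weights glucocorticoid-responsive genes were at 0.0087, oxidative phosphorylation at 0.018, Rps3 at 0.028 and Ptger1 at 0.067. With the hybridization control covariate glucocorticoid-responsive genes were at 0.051, circadian clock genes at 0.092, neuron markers at 0.056, oligodendrocyte markers at 0.011, meningeal markers at 0.020 and Ptger1 at 0.28.

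Leaving out each array gave, for differences whose direction turned, -0.044 to 0.12 for immediate early genes, -0.077 to 0.061 for neuron markers, -0.16 to 0.016 for glucocorticoid-responsive genes, -0.085 to 0.026 for circadian clock genes, -0.0047 to 0.11 for oligodendrocyte precursor markers, -0.40 to 0.058 for acute inflammatory genes, -0.38 to 0.029 for interferon response, -0.049 to 0.060 for astrocyte markers, -0.097 to 0.0024 for ependymal markers, -0.030 to 0.064 for prostanoid genes, -0.34 to 0.077 for meningeal markers and -0.019 to 0.20 for cortical and thalamic markers. For single genes these were -0.18 to 0.24 for Ptgs2, -0.19 to 0.11 for Ptger1, -0.052 to 0.20 for Ptger2, -0.55 to 0.21 for Il6 and -0.027 to 0.47 for Ptges by probe set 1449450_at.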

Other observations

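The test on the genes that fell was chosen after its result was seen, as were the block, the separate sets of arrays, the count of splits by spike-in signal, the comparison of arrays without and with it, the covariate and the intervals of r used here. The other tests were set before their own results were seen, though after the calls they bear on. A further list of 21 genes of striatal projection neurons was written after the first striatal list had passed and before its own test.

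The further striatal list carried the difference to genes outside the first. Of its 17 tested genes 16 were higher in mice labelled knockout, with a median of 0.45, where random lists of like signal gave -0.15 to 0.22. Such random lists draw genes one by one and do not allow for members that move together. Arpp21 was at 2.04 (SE 0.51), the sodium channel subunit gene Scn4b at 2.00 (SE 0.63), the transcription factor gene Bcl11b at 1.38 (SE 0.60) and the cannabinoid receptor gene Cnr1 at 0.73 (SE 0.19), and 0 of the 17 passed the limma threshold over all genes (7 higher and 0 lower at unadjusted p below 0.05). The striatal phosphatase gene Ptpn5 was at -0.34 (SE 0.21), and the list score did not differ beyond the spread between mice (exact permutation test, p = 0.087).

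Interferon and acute inflammatory genes moved together from mouse to mouse. With group means removed, the list scores had a Pearson r of 0.937 over 10 arrays (permutation p = 7e-05, adjusted over 6 relations 0.00042) and a Spearman rho of 0.988 (permutation p = 2e-05, adjusted 0.00012), 0.875 without the 2 arrays farthest from the median and 0.917 within the 7 arrays with spike-in signal. The interferon score also followed blood cell markers, with r of 0.864 (permutation p = 0.00098, adjusted 0.0029) and rho of 0.794 (permutation p = 0.0088, adjusted 0.026), 0.859 without those 2 arrays and 0.898 within the 7. Relations with glucocorticoid-responsive genes (r 0.640, rho 0.673) and meningeal markers (r 0.645, rho 0.733) had adjusted permutation p of 0.069 for both r, and 0.058 and 0.041 for rho.

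Chance was set against the counts by splitting the 10 arrays into 5 and 5 in 100 ways, the labels' own included. As many as 8 genes were called in 3 of the 100, the labels' own among them. That is fewer than the 5 in 100 set beforehand as the mark of chance. But 2 other splits gave more, 40 with only WT replicate 3 and KO replicate 1 exchanged and 49 with 2 arrays of each group exchanged. The count under the labels also fell to 0 under several settings, so this rank alone does not exclude chance. Whether missing spike-in signal adds to such counts stays open: the 3 arrays without it against the 7 with it, genotype as a term, gave 0 genes by limma (847 at unadjusted p below 0.05, reached by 15 of 120 choices of 3 arrays), but of 18 splits that kept those 3 on one side 2 gave 6 and 49, and of 81 others 1 gave 6 or more. With spike-in signal as a block the genotype gave 16 genes, and within the 7 arrays that had it 0. As many as 5 lists were called in 47 of the 100 (highest other 13) and an odds ratio near Ptges as high as 0.953 in 36 (highest other 1.83), so chance cannot be excluded for either.

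The falls of bright genes may come from the array-wide difference in the shape of the signal distribution rather than from genotype. The median difference of the ribosomal list lay at the 8.87th percentile, and that of the oxidative phosphorylation list at the 67.46th, of 10000 random lists of genes of like signal. Neither was thus shown to stand apart from other bright genes. The random lists could hold members of the tested lists themselves, so the test cannot exclude that either list did. With quantile normalization the 6 genes that fell kept 46.4% of their median change, from -0.74 to -0.35, but they did not move alike. Of the bright ones Ndufv3 went from -0.75 to -0.45 and Hcfc1r1 from -0.66 to -0.56, while Stmn1, Pabpn1 and Ndufb11 were at -0.12, -0.24 and -0.06. The dimmer Csf2ra was at -1.05. The amount of labelled RNA cannot be told apart from genotype. Hybridization controls averaged lower in arrays labelled knockout, so they partly follow the group, though the groups overlap (exact permutation test, p = 0.040, adjusted over the array measures 0.086). With them as a covariate the ribosomal score difference was 124% of its size, at -0.29, but its 95% interval, -0.60 to 0.03, includes 0 (camera with its preset correlation called the list there too, at -0.28). An effect of genotype on these genes stays open, as untested.

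The striatal difference may be chance, a larger share of striatal tissue in the samples labelled knockout, or an effect of genotype on these neurons. Chance is not excluded, with an exact permutation test p of 0.079 for the list score. Camera with an estimated correlation gave an adjusted p of 0.646. The shape of the distribution is argued against, since the first list kept its size with quantile normalization, at 0.48 against 0.51 as deposited. It also lay at the 100th percentile of 10000 lists of like signal. Those random lists draw genes one by one, so a list whose members move together can lie far out without a group difference. The acute inflammatory list lay at the 0.23rd percentile, with an exact permutation test p of 0.667. The further list also lay at the 100th percentile. A larger share of striatal tissue and an effect of genotype on these neurons both predict this, so it does not tell them apart. Both lists hold genes of striatal neurons measured on the same arrays, so the further list gives little separate support. Dlk1 at -0.43 (SE 0.14), lower when adjusted over its list alone, Ptpn5 at -0.34 (SE 0.21) and Rgs9 at -0.25 (SE 0.22) did not follow. Zic1, Pde7b and Rxrg stayed near 0 (-0.0041, 0.0060 and 0.07). Striatal and septal members of the first list were not told apart, so Dlk1 and Zic1 need not mark striatum. Of the tested genes 4 of 15 on the first list and 2 of 17 on the further one are on another list too, and all were measured in the preoptic samples themselves. The difference rests on few arrays, with scores of 9.38, 9.15 and 9.39 in KO replicates 1 to 3, 8.38 and 8.66 in KO replicates 4 and 5, and 8.27 to 8.62 in those labelled wild-type. Chance and a dissection difference therefore both remain open.

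The spread of interferon genes between mice could come from the share of microglia and vessel cells or from the amount of labelled RNA. Its r with the mean of microglia and endothelial scores was 0.235 (rho 0.115, permutation p 0.51 and 0.76, and 0.514 and 0.892 adjusted), 0.571 without the 2 farthest arrays and 0.358 within the 7. Its r with the hybridization controls was -0.353 (rho -0.05, permutation p 0.31 and 0.89, and 0.377 and 0.892 adjusted), 0.04 without those 2 arrays and 0.08 within the 7. With 10 arrays the 95% intervals of r, -0.51 to 0.78 and -0.82 to 0.41, are too wide to exclude either. The interferon score followed blood cell markers more closely, with r of 0.864 and rho of 0.794, and no explanation of that relation was tested. Differences in how strongly each mouse responded to LPS stay open, as untested, since no measure of the dose received or of fever was used here.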
